A study of Mus musculus with 18 samples.

How the data were processed

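Gene expression was measured on Illumina BeadChip arrays in haematopoietic stem cells (HSCs) from the bone marrow of mice, 18 h after treatment with PBS, interferon alpha (IFNa) or lipopolysaccharide (LPS). Each of the 3 groups held 6 arrays, which the series text calls biological replicates, so the p-values of single genes measure the spread between these 18 samples. Per the design text of the series, marrow was depleted of cells bearing lineage markers, and cells without these markers that carried Kit and CD150 and lacked CD48 were then sorted. Per the labels' protocols, RNA was extracted with the PicoPure or the RNeasy Micro kit, amplified with the Ovation Pico system and labelled with biotin. Which kit served which sample, and which samples shared a chip or a sorting session, is not given in the sources used here.

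The authors deposited a non-normalized signal intensity for each of 46237 probes on each array, on a linear scale and not background-subtracted. The deposited intensities had medians of 187 to 236 per array, a lowest value of 117 to 144 and a highest value of 72721.5 to 74449. Beside each intensity the authors deposited a detection p-value, whose method is not given in the sources used here. A further deposited table holds the authors' processed values, also an intensity on a linear scale, with medians of 142 to 146 per array. How the authors scaled these processed intensities is not given in the sources used here, and this table served only as an alternative. Each of its columns correlated with its own non-normalized array at 0.997 to 0.999 and with any other array at 0.969 or less.

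Intensities were processed with limma 3.58.1 in R 4.3.3 by the neqc method. It estimates the background of each array from the detection p-values, applies a normexp correction with an offset of 16, scales the arrays by quantiles and takes log2. Estimated background means were 172 to 222. At a detection p under 0.01, 18930 to 22146 probes were detected per array, which is 40.9 to 47.9% of them. Probes detected on at least 6 of the 18 arrays, in whatever groups, were kept, which left 23390 and removed 22847. Near the background a fold change is compressed by the offset, and quantile scaling gives all arrays the same distribution, so a shift of most genes one way would be removed.

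Of the 46237 probes, 35784 had 1 gene symbol in the platform annotation, 0 had several and 10453 were not listed there and stayed unnamed. Symbols were brought to those of the RefSeq annotation of GRCm38.p6, by gene number for 28620 probes, by transcript accession for 2637, by symbol for 2128 and by a unique synonym for 2343, and 56 kept the listed symbol. A gene took the brightest of its kept probes over all 18 arrays, which concerned 4737 genes with more than 1. This gave 15899 features, of which 11826 were named genes and 4073 unnamed probes. Genome coordinates are not printed because the arrays' build is not given in the sources used here. Complement C4a and C4b are near-identical copies that a probe may not tell apart.

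Groups were compared with limma's lmFit and eBayes on log2 values, in 1 model with a mean per group over all 18 arrays. Tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Error terms of log2 changes are the model's standard errors, and levels are given as mean ± SD. Where a probe was not detected on any array of a group, the fold is given as a lower bound. That bound sets the brighter group's mean against the mean, per array, of the lowest signal among detected probes or the probe's own signal, whichever is higher. The precision is limited by the 6 arrays per group.

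The 3 comparisons, the model, the filter, the gene lists and the rule for naming genes were fixed before the data were examined. There were 21 lists of pathways and functions and 7 of markers of other cell types. Each list was tested with limma's camera, with a preset correlation between genes of 0.01, and adjusted over all 84 tests. These p-values set a list against the other genes and take little account of members that vary together between samples. Camera with an estimated correlation and fry, a test of whether a list moves 1 way on balance, were alternatives. Counts of changed members are given over all genes tested and adjusted over the list alone.

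The rule named the 10 largest rises and the 10 largest falls among changed genes whose 6 samples of the first group all lay on 1 side of the second group's mean. It also named up to 4 members of each list, and Ly6a, Kit, Slamf1, Cd48, Ifnar1, Ifnar2 and Tlr4. It gave 159 calls, of which 103 were kept in all 18 fits that each left out 1 array. Of the changed genes, values are printed for a part of these 103, and for others only beside a statement of what ends their call or that they were chosen after their values were seen. This selection was made after the fits were seen. Values of genes that did not pass the test are given without a direction.

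Comparisons with the same 6 PBS arrays share their chance values. The overlap and the correlation of the treatments were therefore set beside 100 simulations of unchanged groups and beside fits in which the PBS arrays were split into 3 and 3. On simulated data, with 50 of the 15899 genes changed at each size, the model recovered 6% of changes of log2 0.5, 32% of 1, 62% of 1.5 and 86% of 2 in IFNa against PBS, with 1 false call. For LPS against PBS these shares were 6%, 40%, 68% and 74%, with 4 false calls. The simulation gave all groups the same spread and independent noise, so the 2 comparisons differ only by the genes and noise drawn. It changed fewer genes than were called in the data, so the shares recovered there may differ.

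The alternatives were an offset of 50, no background correction, cyclic loess or median scaling, the authors' processed table, no filter, detection on all 18 arrays, a detection p of 0.05, the mean of a gene's probes, the replicate number as a block, only the compared groups, eBayes with trend and robust, array weights, a 2-fold minimum and each array left out. Alternatives chosen after seeing the data left out the 4 arrays of lowest weight, took the granulocyte marker score as a covariate, or took the numbers 1 to 3 against 4 to 6 as a covariate.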

Results

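Haematopoietic stem cells (HSCs) are the rare marrow cells from which all blood cells are formed. Wildtype mice were given phosphate-buffered saline (PBS) as the control, interferon alpha (IFNa), an antiviral cytokine, or lipopolysaccharide (LPS), the bacterial cell-wall component that signals through Tlr4. Marrow was taken 18 h later, and cells without lineage markers that carried Kit and CD150 and lacked CD48 were sorted and their RNA was hybridised to Illumina arrays. Each treatment had 6 arrays. Between 18930 and 22146 of 46237 probes were detected per array, and 15899 features were tested, of which 11826 were named genes.

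The 18 arrays separated by treatment. On a principal component analysis of the 2000 most variable genes, the first component held 14.6% of the variance, with PBS arrays at −34.7 to −23.2 and treated arrays at 0.774 to 34.8. The other component, with 10.2%, held IFNa arrays at 0.458 to 51.4 and LPS arrays at −24.7 to −13.2. Correlations within a group, over 15 pairs each, were 0.924 to 0.940 for PBS, 0.870 to 0.937 for IFNa and 0.879 to 0.924 for LPS. The arrays with the lowest weights were LPS replicates 1 and 2 (0.572 and 0.574) and IFNa replicates 4 and 1 (0.584 and 0.664).

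**Figure D1:**
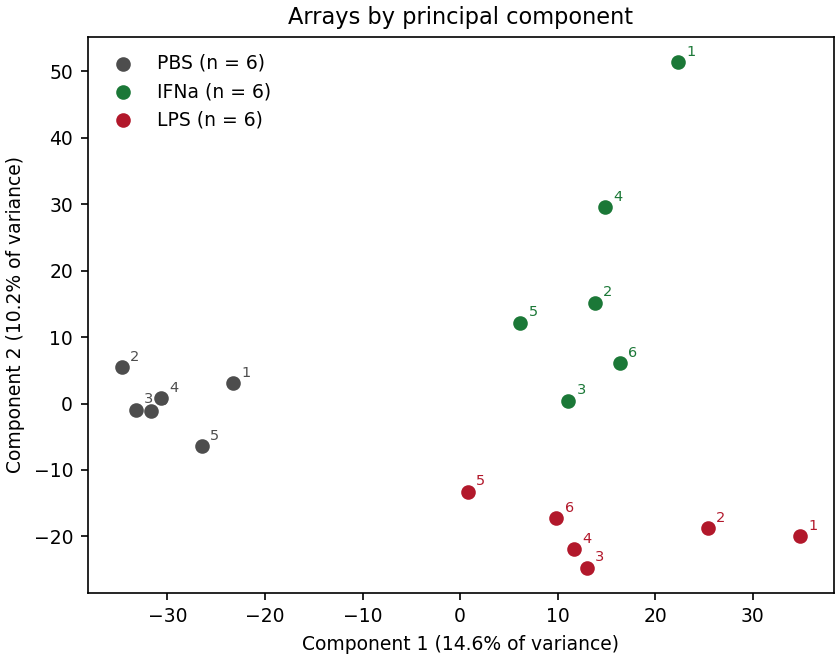
Principal components 1 and 2 of the 18 arrays over the 2000 most variable genes, each point 1 array with its replicate number, coloured by treatment. PBS arrays lie at −34.7 to −23.2 on the first component and treated arrays at 0.774 to 34.8.

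The first comparison asked what IFNa changed in these cells. Antiviral genes rose most. Isg15, a ubiquitin-like protein attached to other proteins, rose from 6.78 ± 0.75 to 11.85 ± 0.22 on the log2 scale (mean ± SD, n = 6), a change of 5.06 (SE 0.29, adjusted p = 2.82e-08). Oas2, an oligoadenylate synthetase that senses double-stranded RNA, rose by 4.98 (SE 0.39, adjusted p = 3.52e-07), and the chemokine Cxcl10 by 5.24 (SE 0.72, adjusted p = 0.000221), or by 2.27 on its other probe (adjusted p = 0.00305). The deepest falls were in Matn4, an extracellular matrix protein, which fell by 5.37 (SE 0.83, adjusted p = 0.000816), and Rprm, which fell by 4.13 (SE 0.31, adjusted p = 2.81e-07). Rprm was detected on 0 of 6 IFNa arrays and was at least 15.6-fold lower there.

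In all, 574 features changed with IFNa, 331 up and 243 down (57.7% up), by limma at an adjusted p under 0.05. Of the named genes, 254 rose and 209 fell. Median scaling gave 69.4% up, whereas falls were the larger part with no background correction (49.7% up) and the authors' processed table (48.0% up). Log2 changes depend on the background step: of 160 gene calls examined over the 3 comparisons, 84 had a log2 change smaller by over 1.5 times with no background correction and 116 with the authors' processed table.

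Of 36 measured type I interferon antiviral genes, 32 rose and 1 fell (35 and 1 when adjusted over the list alone), with a median change of 2.36 (camera adjusted p = 5.19e-63). Ifit3 rose by 4.39 (SE 0.34, adjusted p = 2.81e-07), and Usp18, the protease that removes Isg15, by 4.16 (SE 0.34, adjusted p = 5.25e-07). The member that fell, Ifi27, had a change of −0.45 and an adjusted p of 0.0472, and its call was lost in 16 of the 18 fits that each left out 1 array, with adjusted p up to 0.105. Guanylate-binding proteins and immunity-related GTPases, which attack the vacuoles of microbes inside cells, rose in 11 of 12 members (12 adjusted over the list alone), with a median of 1.57 and a camera adjusted p of 5.79e-22. Gbp3 went from 8.76 ± 0.37 to 11.23 ± 0.34 (n = 6, adjusted p = 3.91e-07), and Igtp rose by 2.29 (SE 0.23, adjusted p = 6.43e-06).

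Genes of antigen presentation rose with IFNa. Of 18 measured MHC class I and immunoproteasome genes, 12 rose (15 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 2.51e-15). H2-T22 rose by 1.52 (SE 0.17, adjusted p = 2.08e-05) and H2-T10 by 1.12 (SE 0.17, adjusted p = 0.000587), while other probes of H2-T10 gave 1.27 (adjusted p = 0.0782) and 1.47 (adjusted p = 0.0609). Of 9 MHC class II genes, 3 rose (5 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 2.31e-05, and adjusted p = 0.0866 with an estimated correlation). These were H2-Eb1 at 2.88 (SE 0.28, adjusted p = 4.47e-06), H2-Aa at 1.92 (SE 0.24, adjusted p = 7.58e-05) and H2-Ab1 at 1.25 (SE 0.26, adjusted p = 0.0103), with 2.11 and 0.96 on its other probes.

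Genes of stem cells fell as a list, by smaller amounts. Of 26 measured HSC genes 1 fell, Fhl1, a LIM domain protein, by 0.87 (SE 0.19, adjusted p = 0.0146), and 1 when adjusted over the list alone. The list's median was −0.35 (camera adjusted p = 0.000551, and adjusted p = 0.204 with an estimated correlation), and with median scaling the adjusted p of Fhl1 was 0.0862. The 16 quiescence and CDK inhibitor genes had a median of −0.44, with 0 called over all genes by limma and 1 up and 5 down adjusted over the list alone (camera adjusted p = 0.00935, and adjusted p = 0.204 with an estimated correlation). Kit, the receptor of stem cell factor and part of the gate, fell by 0.93 (SE 0.14, adjusted p = 0.000876), and Vwf, a clotting protein, by 1.14 (SE 0.20, adjusted p = 0.0024). With the mean of each gene's probes these were −0.49 (adjusted p = 0.118) and −0.67 (adjusted p = 0.348), and another probe of Kit gave 0.06. Chst2, a sulfotransferase, fell by 2.92 (SE 0.50, adjusted p = 0.00229). Itga9, an integrin chain, fell by 3.40 (SE 0.66, adjusted p = 0.00671), while its other probe gave −0.94 (adjusted p = 0.0989).

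Other lists passed camera with smaller medians. The 20 MYC and ribosome biogenesis genes had a median of 0.22, with 0 called over all genes and 2 up adjusted over the list alone (camera adjusted p = 0.00319, and adjusted p = 0.144 with an estimated correlation). The 20 cytosolic ribosomal protein genes had a median of −0.08, with 0 called over all genes and 1 down adjusted over the list alone (camera adjusted p = 0.0471, and adjusted p = 0.292 with an estimated correlation). This call was lost in 9 of the fits without 1 array (adjusted p up to 0.113) with median scaling (adjusted p = 0.462) and with the granulocyte marker level as a covariate (adjusted p = 0.0815), and the median was −0.12 without PBS replicate 4 and −0.14 without IFNa replicate 3. Of 25 p53 target and cell death genes 4 rose (7 up and 2 down adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0373, and adjusted p = 0.196 with an estimated correlation). Among them, Mlkl, the pore-forming protein of necroptosis, rose by 1.38 (SE 0.28, adjusted p = 0.00858) and Daxx by 1.64 (SE 0.20, adjusted p = 5.34e-05). The list's call was lost without PBS replicate 1, PBS replicate 5 or IFNa replicate 4, with adjusted p up to 0.165, and its median was 0.16 without PBS replicate 3, 0.44 without PBS replicate 4 and 0.13 without IFNa replicate 4. Without the 4 arrays of lowest weight the ribosomal protein (adjusted p = 0.141) and p53 (adjusted p = 0.104) lists did not pass and the 12 erythroid markers did, with a median of 0.52 (adjusted p = 0.00901).

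The remaining 19 lists did not pass camera with IFNa, at adjusted p of 0.189 to 0.983. The 25 mitotic genes had a median of 0.00 and the 27 DNA replication genes one of 0.02, with 0 called by limma in either, over all genes or over the list alone. The 21 NF-kB targets had a median of 0.13 with 1 called, Ccl5 at 3.03 (SE 0.38, adjusted p = 7.32e-05), and the 13 STAT3 and acute-phase genes a median of 0.16 with 0 called. The 12 granulocyte markers had a median of −0.66 with 0 called, and of −1.09 to −0.28 in the fits without 1 array, where the list passed without IFNa replicate 6 (adjusted p = 0.0495). Erythroid markers passed without IFNa replicate 4 (adjusted p = 0.0395). The mean log2 level of the granulocyte markers was 6.42 ± 0.98 on IFNa arrays and 7.09 ± 1.14 on PBS arrays (n = 6).

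The comparison of LPS with PBS asked what a bacterial signal changed. Saa3, a serum amyloid A protein of the acute phase, rose from 4.96 ± 0.30 to 9.26 ± 1.32 (n = 6), a change of 4.30 (SE 0.43, adjusted p = 1.44e-05). The chemokine Ccl5 rose by 4.06 (SE 0.38, adjusted p = 6.81e-06), and Cfb, complement factor B, by 3.30 (SE 0.38, adjusted p = 6.16e-05), which was at least 9.28-fold, since it was detected on 0 of 6 PBS arrays. Pf4, a platelet chemokine, fell from 11.77 ± 0.15 to 8.96 ± 0.37, a change of −2.81 (SE 0.18, adjusted p = 1.28e-07). Ptn, a secreted growth factor, fell by 4.24 (SE 0.38, adjusted p = 4.56e-06), and Rprm had a change of −4.10 (SE 0.31, adjusted p = 1.14e-06). Matn4 fell from 11.69 ± 0.54 to 6.69 ± 2.05 (adjusted p = 0.00183).

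With LPS 1440 features changed, 641 up and 799 down (44.5% up), by limma at an adjusted p under 0.05. Of the named genes, 488 rose and 649 fell. Median scaling gave 25.7% up, with the median of all genes at −0.11. Without the 4 arrays of lowest weight 920 features changed, and leaving out PBS replicate 2 gave 896 and PBS replicate 3 gave 922.

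Of 36 antiviral genes 29 rose with LPS (30 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 1.33e-27). Oas2 rose by 4.17 (SE 0.39, adjusted p = 7.72e-06) and Ifit3 by 3.17 (SE 0.34, adjusted p = 2.17e-05), while the other probe of Ifit3 gave 1.25 (adjusted p = 0.121). Of 12 GTPases 10 rose, and 10 adjusted over the list alone, with a median of 1.40 (camera adjusted p = 2.93e-12, and adjusted p = 0.08 with an estimated correlation). Gbp3 rose by 2.09 (SE 0.20, adjusted p = 7.72e-06). Of 18 MHC class I genes 9 rose (13 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 6.18e-08). Nlrc5, an activator of these genes, rose by 0.79 (SE 0.15, adjusted p = 0.00368) and the peptide transporter Tap2 by 0.87 (SE 0.19, adjusted p = 0.00941). Of 9 MHC class II genes 4 rose (5 up and 1 down adjusted over the list alone), with a median of 1.08 (camera adjusted p = 0.00351, and adjusted p = 0.231 with an estimated correlation). Cd74, the invariant chain, rose by 3.27 (SE 0.75, adjusted p = 0.0135) and H2-Eb1 by 2.67 (SE 0.28, adjusted p = 1.96e-05).

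**Figure D2:**
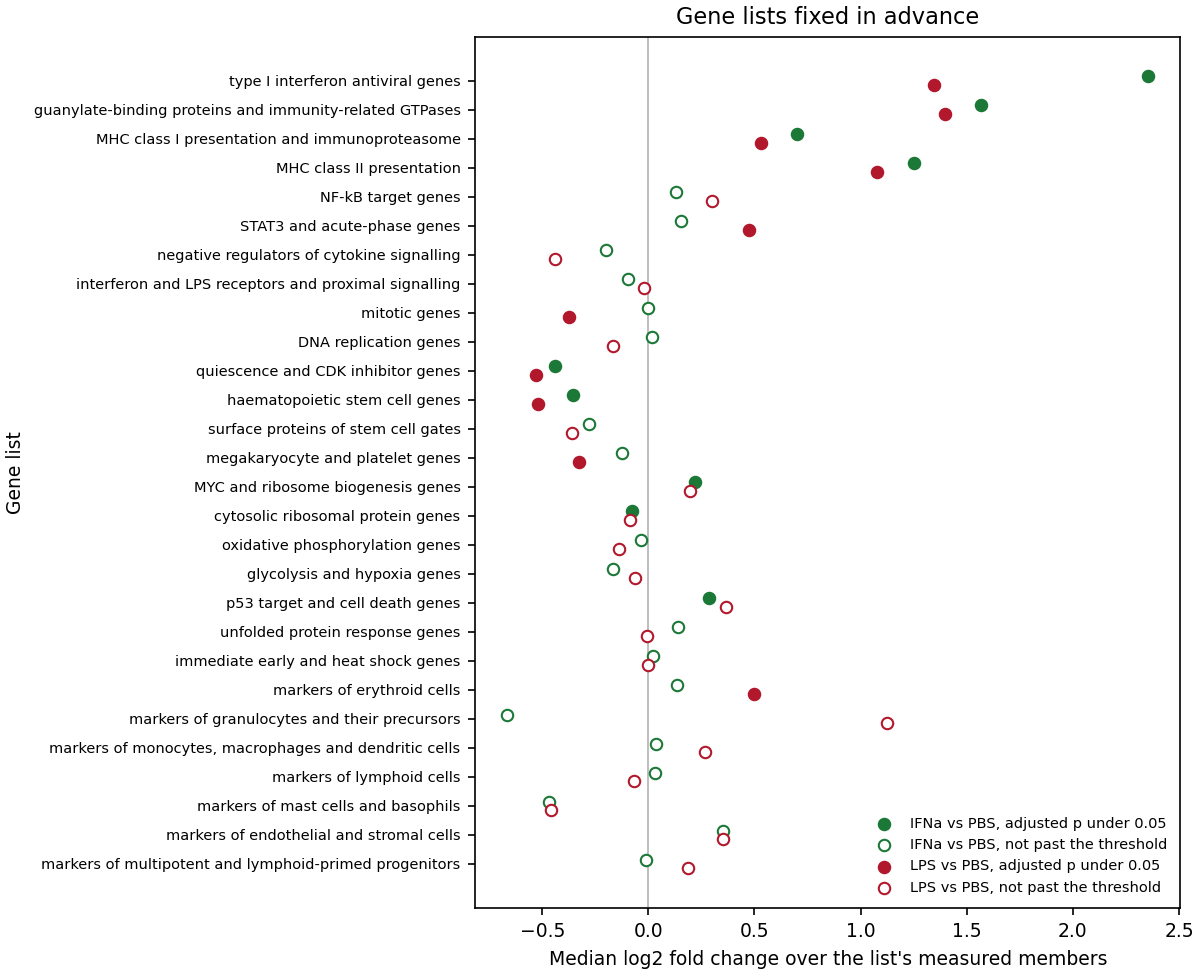
Median log2 fold change of each of the 28 gene lists with IFNa and with LPS, each against PBS; filled points passed camera at an adjusted p under 0.05. The antiviral list lies at 2.36 with IFNa and 1.34 with LPS.

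Of 13 STAT3 and acute-phase genes 4 rose with LPS, and 4 adjusted over the list alone, with a median of 0.48 (camera adjusted p = 0.0336, and adjusted p = 0.276 with an estimated correlation). Beside Saa3 these were Socs3, an inhibitor of cytokine signalling, at 2.30 (SE 0.42, adjusted p = 0.00333), Lcn2 at 1.76 (SE 0.53, adjusted p = 0.0477) and Lrg1 at 0.98 (SE 0.27, adjusted p = 0.0309). Lcn2, a protein that binds bacterial iron carriers, lost its call in 16 of the 18 fits without 1 array (adjusted p up to 0.0878), and Lrg1 without PBS replicate 2, 3 or 6 or LPS replicate 2 (adjusted p up to 0.0703). The list lost its call without PBS replicate 6, LPS replicate 4 or LPS replicate 5 (adjusted p up to 0.0706), with no background correction (adjusted p = 0.0787), with the authors' table (adjusted p = 0.0779) and with the granulocyte marker level as a covariate (median 0.31, adjusted p = 0.0601). Its median was 0.31 without PBS replicate 3 and 0.21 without LPS replicate 4. Granulocyte markers varied among the same arrays. Their mean log2 level was 7.71 ± 1.60 on LPS arrays, 5.76 to 9.82, against 7.09 ± 1.14 on PBS arrays, 6.10 to 8.83 (n = 6). Arrays numbered 4 to 6 lay above those numbered 1 to 3 in each group, with 9.06 ± 0.74 against 6.35 ± 0.61 for LPS and 7.92 ± 1.09 against 6.26 ± 0.15 for PBS (n = 3). This division was chosen after the values were seen. Of the 12 granulocyte markers 1 rose with LPS, Ms4a3 at 1.37 (SE 0.35, adjusted p = 0.0213), with a list median of 1.12, or 0.43 to 1.60 in the fits without 1 array (camera adjusted p = 0.386). With the mean of its probes Ms4a3 was at 0.84 (adjusted p = 0.289), and without the 4 arrays of lowest weight the list's adjusted p was 0.0218.

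**Figure D3:**
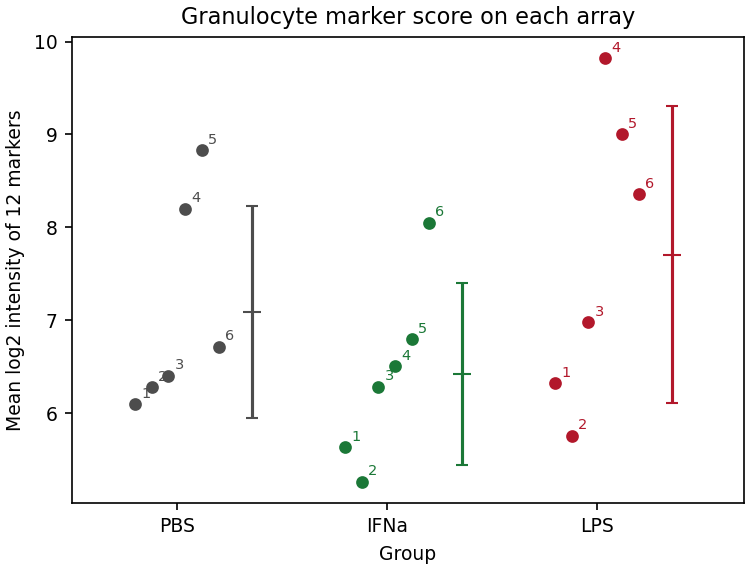
Mean log2 intensity of the 12 measured granulocyte markers on each array, by treatment, with the group mean and SD. LPS arrays range from 5.76 to 9.82, PBS arrays from 6.10 to 8.83 and IFNa arrays from 5.26 to 8.05.

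Of 26 HSC genes 5 fell with LPS (12 adjusted over the list alone), with a median of −0.52 (camera adjusted p = 1.68e-05, and adjusted p = 0.112 with an estimated correlation). Fhl1 fell by 1.54 (SE 0.19, adjusted p = 0.000107) and Angpt1, a ligand of the receptor Tek, by 1.64 (SE 0.30, adjusted p = 0.00383). Of 22 megakaryocyte and platelet genes 7 fell (1 up and 7 down adjusted over the list alone), with a median of −0.33 (camera adjusted p = 0.00153, and adjusted p = 0.19 with an estimated correlation). Vwf fell from 10.78 ± 0.21 to 8.56 ± 0.39 (n = 6, limma adjusted p = 4.12e-06), while its other probe gave −0.76 (adjusted p = 0.583). Of 16 quiescence and CDK inhibitor genes 3 fell (5 adjusted over the list alone), with a median of −0.53 (camera adjusted p = 0.000237, and adjusted p = 0.08 with an estimated correlation). The CDK inhibitor Cdkn2d fell by 1.16 (SE 0.27, adjusted p = 0.0145) and the growth suppressor Ndn by 1.80 (SE 0.43, adjusted p = 0.0167).

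Mitotic genes also passed camera as a list with LPS, although 12 of 100 splits of the arrays gave a camera p as small. Of 25, 3 fell, and 3 adjusted over the list alone, with a median of −0.37 (camera adjusted p = 0.00291, and adjusted p = 0.276 with an estimated correlation). Cdk1, the kinase that starts mitosis, fell by 0.80 (SE 0.20, adjusted p = 0.0183), a call lost with the mean of its probes (adjusted p = 0.187) and without the 4 arrays of lowest weight (adjusted p = 0.0553). The 12 erythroid markers had a median of 0.50, with 2 up and 1 down over all genes and 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.00703, and adjusted p = 0.423 with an estimated correlation). The red cell genes Blvrb and Rhag were up and Icam4 was down, and none of the 3 kept its call in every fit without 1 array.

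The remaining 18 lists did not pass camera with LPS, at adjusted p of 0.0926 to 0.983. NF-kB targets had a median of 0.30 with 2 up and 1 down, among them Cd40, a costimulatory receptor, at 0.96 (SE 0.19, adjusted p = 0.00581). The 28 oxidative phosphorylation genes had a median of −0.14 with 1 up and 2 down, and the 27 DNA replication genes a median of −0.16 with 2 down. Tlr4 was at 7.46 with PBS and 5.80 with LPS, a difference of −1.66 (SE 0.67) that did not pass the test (adjusted p = 0.131). Slamf1 (CD150) and Ifnar2 did not pass in any comparison, Cd48 and Ifnar1 were below the detection filter, and Ly6a had no named probe.

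**Figure D4:**
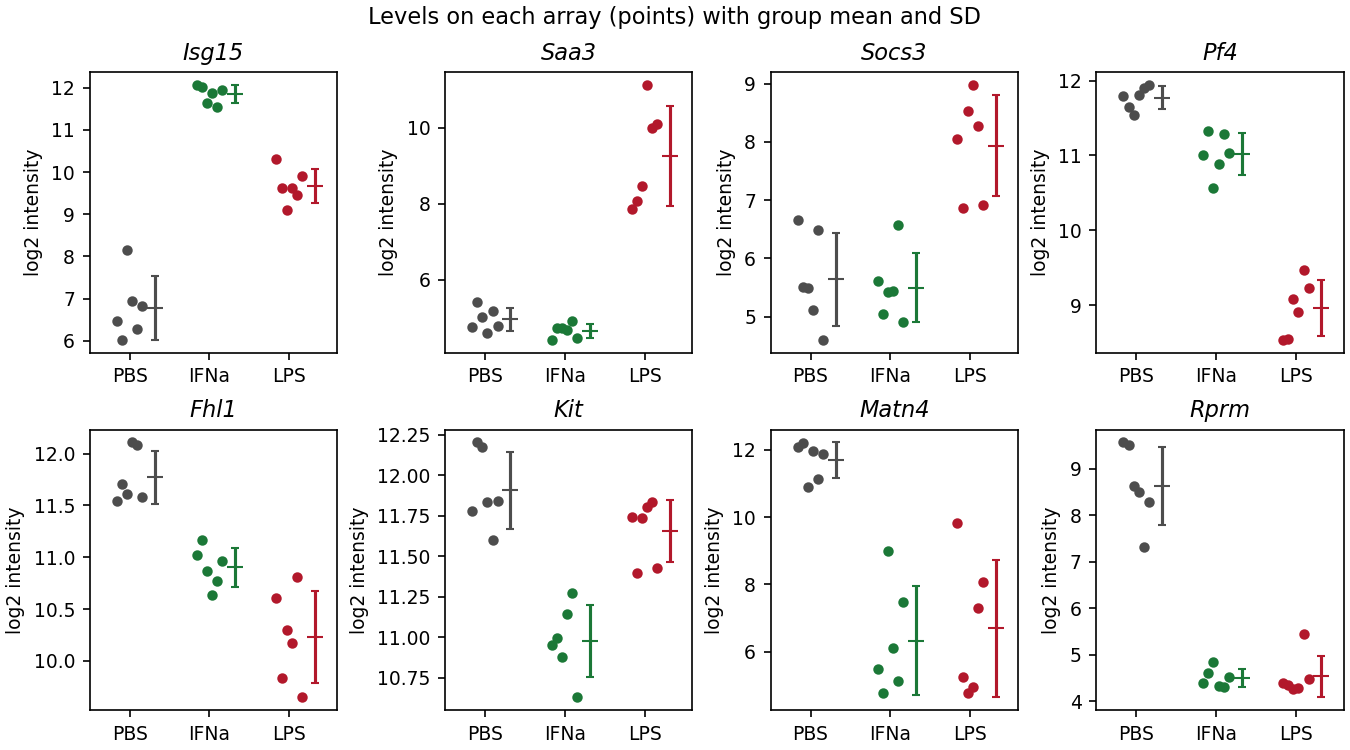
Log2 intensity of Isg15, Saa3, Socs3, Pf4, Fhl1, Kit, Matn4 and Rprm on each array, by treatment, with the group mean and SD. Saa3 averages 9.26 with LPS and 4.96 with PBS, and Pf4 8.96 and 11.77.

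The direct comparison of LPS with IFNa asked where the treatments differed. Saa3 was higher with LPS, at 9.26 ± 1.32 against 4.65 ± 0.18 (n = 6), a difference of 4.61 (SE 0.43, adjusted p = 4.12e-05). It was detected on 0 of 6 IFNa arrays and was at least 23.1-fold higher with LPS. Socs3 was higher by 2.44 (SE 0.42, adjusted p = 0.00882). Antiviral genes were lower with LPS than with IFNa, among them Isg15 at −2.18 (SE 0.29, adjusted p = 0.00156) and Mx1, a GTPase that blocks viruses, at −2.05 (SE 0.29, adjusted p = 0.00312). Pf4 was lower by a log2 difference of −2.05 (SE 0.18, adjusted p = 1.85e-05) and Ptn by one of −2.46 (SE 0.38, adjusted p = 0.00489).

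Between LPS and IFNa 212 features differed, 72 higher and 140 lower with LPS (34.0% higher), by limma at an adjusted p under 0.05. With only the compared groups in the model 87 features differed, 24 higher and 63 lower with LPS. Median scaling gave 587 features, 14.0% of them higher, with the median of all genes at −0.14. Without the 4 arrays of lowest weight 64 differed, and leaving out 1 array gave 99 without LPS replicate 3, 105 without IFNa replicate 1, 118 without IFNa replicate 2, 120 without IFNa replicate 5 and 141 without LPS replicate 6. Without those 4 arrays the adjusted p of Socs3 was 0.051.

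Of 36 antiviral genes 10 were lower with LPS (1 up and 30 down adjusted over the list alone), with a median of −0.95 (camera adjusted p = 2.66e-22). Of 22 megakaryocyte and platelet genes 4 were lower (5 adjusted over the list alone), with a median of −0.30 (camera adjusted p = 0.00018, and adjusted p = 0.112 with an estimated correlation). Mitotic genes had a median of −0.37 with 1 of 25 lower, the cyclin Ccna2 at −1.02 (SE 0.20, adjusted p = 0.0174), and 3 adjusted over the list alone (camera adjusted p = 1.2e-05, and adjusted p = 0.112 with an estimated correlation). With the granulocyte marker level as a covariate Ccna2 was at −0.90 (adjusted p = 0.0576).

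The GTPases had a median of −0.41, with 0 of 12 called over all genes and 4 down adjusted over the list alone (camera adjusted p = 0.00294, and adjusted p = 0.425 with an estimated correlation). MHC class I genes had a median of −0.15, with 0 of 18 called over all genes and 2 down adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.383 with an estimated correlation). Erythroid markers had a median of 0.34 with 0 of 12 called either way (camera adjusted p = 0.0198, and adjusted p = 0.451 with an estimated correlation). Granulocyte markers had a median of 1.23, with 0 of 12 called over all genes and 1 up adjusted over the list alone (camera adjusted p = 0.00351, and adjusted p = 0.427 with an estimated correlation). The MHC class I call was lost without IFNa replicate 4 or LPS replicate 4 (adjusted p up to 0.0943) and the erythroid call without IFNa replicate 4 or LPS replicate 1 (adjusted p up to 0.174). Without IFNa replicate 4 the erythroid median was 0.21 and the GTPase median −0.25. With the granulocyte marker level as a covariate the MHC class I call was lost (adjusted p = 0.0851), as was that of the granulocyte markers, which make up the covariate (adjusted p = 0.684), and HSC genes passed (median −0.29, adjusted p = 0.0140). Without the 4 arrays of lowest weight the adjusted p of the GTPases was 0.0753, of MHC class I genes 0.0506 and of erythroid markers 0.968, while 5 lists passed that did not with all arrays: STAT3 (adjusted p = 0.0115), DNA replication (0.0242), glycolysis (0.0290) and oxidative phosphorylation genes (0.0299) and progenitor markers (0.0218). The other 21 lists did not pass camera, at adjusted p of 0.071 to 0.983, but with median scaling 6 of them did, among them oxidative phosphorylation (adjusted p = 0.000888) and DNA replication genes (adjusted p = 0.00356). Leaving out 1 array, STAT3 genes passed without LPS replicate 1 or 2, DNA replication genes without LPS replicate 2 or 6, HSC genes without LPS replicate 5, MYC genes without LPS replicate 2, oxidative phosphorylation genes without IFNa replicate 4 and progenitor markers without IFNa replicate 1 or 3 or LPS replicate 2, at adjusted p of 0.0135 to 0.0495. Over all 84 list tests, median, mean and test differed in sign in 11, of which 0 passed camera. These were NF-kB targets, negative regulators, mitotic and immediate early genes with IFNa, immediate early genes and lymphoid and mast cell markers with LPS, and quiescence genes and monocyte, lymphoid and endothelial markers between LPS and IFNa. Of the 26 list tests that passed, 6 held with an estimated correlation: antiviral genes in all 3 comparisons, MHC class I genes with IFNa and with LPS, and GTPases with IFNa.

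**Figure D5:**
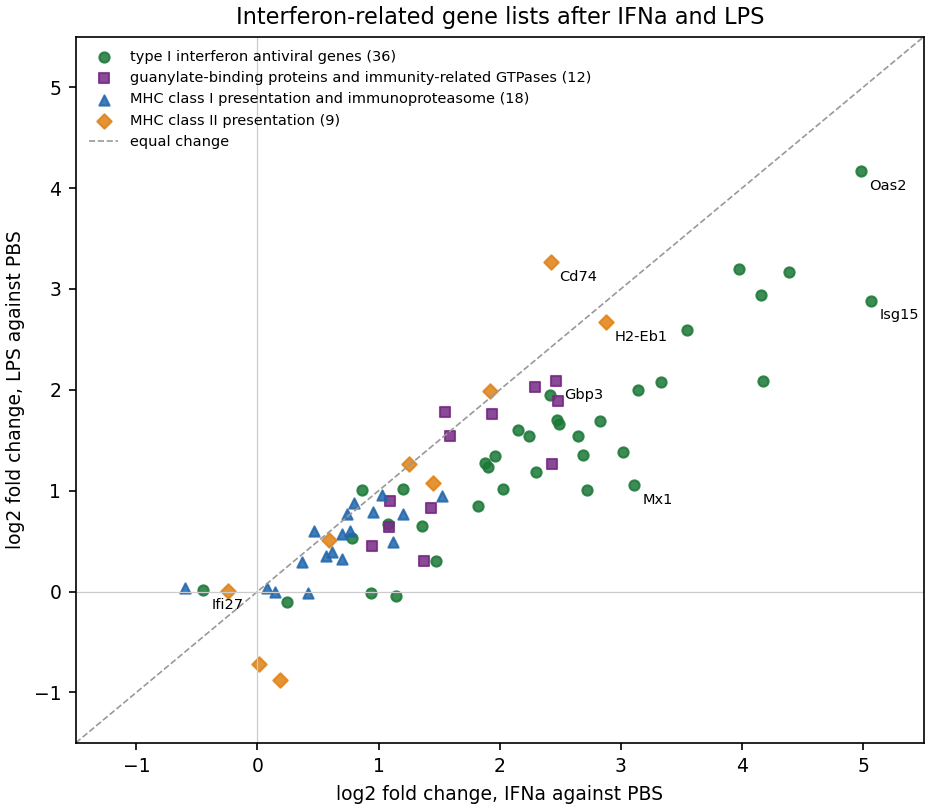
Log2 fold change with LPS against that with IFNa, each against PBS, for the measured members of the antiviral (36), GTPase (12), MHC class I (18) and MHC class II (9) lists; the dashed line marks equal change. The antiviral list has a median of 2.36 with IFNa and 1.34 with LPS.

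The responses to IFNa and LPS overlapped. Of the 574 features changed with IFNa, 357 (62.2%) also changed with LPS, 199 up in both and 157 down in both, against 13.3 and 12.2 for independent lists of these sizes. The number down in both was 85 without PBS replicate 3, 86 without PBS replicate 2, 94 without PBS replicate 6 and 104 without IFNa replicate 6. It was 97 with median scaling, 104 with the replicate number as a block, 246 with array weights, 260 with no background correction and 286 with the authors' table, and with a 2-fold minimum 105 were up and 70 down. In 100 simulations of unchanged groups against shared PBS arrays the overlap averaged 0.01 up and 0 down, where only 0.52 and 0.13 features were called on average, so this value sets no level for an overlap of longer lists. With the PBS arrays split, 3 for each treatment, over 20 assignments, 75.2 features were up in both (68 to 85) and 19.9 down in both (16 to 30), against 2.19 and 0.799 for independent lists of those sizes. The 1 feature that changed in opposite directions, Them7, named after its values were seen, was at −0.88 with IFNa (adjusted p = 0.0117) and 0.94 with LPS (adjusted p = 0.00586). Across all genes, which are not independent replicates, the fold changes correlated with a Pearson r of 0.626 and a Spearman rho of 0.571. Unchanged groups gave an r of 0.469 ± 0.228 by simulation, −0.28 to 0.86, and the split PBS arrays gave 0.390 (0.370 to 0.406). The covariance was 0.228, against 0.0770 ± 0.0482 simulated, a difference of 0.151, but the simulated values ranged from −0.0318 to 0.244 and so reached above it.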

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

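Of the tests in this part, those of Saa3, Socs3, Lcn2 and Lrg1 with the marker covariate were written before their values were seen, and the others, with the changes less 2 SE and the fits of these genes that also leave out 1 array, were chosen only after the result was seen.

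Granulocyte markers varied between arrays of 1 group, and on arrays numbered 4 to 6 their mean log2 level was above that on arrays numbered 1 to 3 in PBS (lowest 6.72 against highest 6.40), IFNa (6.51 against 6.29) and LPS (8.36 against 6.98), which chance gives in 0.0125% of cases for a division named in advance, as this was not. A candidate explanation is granulocyte-lineage cells or RNA that passed the lineage depletion and the gate: the 12 markers, of which 6 were detected on all PBS arrays and 0 are in another list, deviated together with a mean pairwise r of 0.455, above the highest of 1000 random lists (0.155), and, given as levels only, S100a9, an abundant transcript of these cells, was at 8.88 with PBS and 10.44 with LPS and Mpo at 10.15 and 9.50. For a batch between the numbers, limma gave 884 genes at an unadjusted p under 0.05 and 0 at an adjusted p. This lay within the 588 to 1389 of the other 9 divisions (0 to 1 adjusted), and above their median of 765. The divisions above it (907, 1010 and 1389) also kept numbers 1 and 2 together, while those that parted 1 and 2 gave 588 to 789. Divisions that share arrays in this way set no level for a batch, so a batch stays open, although no single gene passed at an adjusted p. A lower share of stem cells is argued against as the whole cause by 21 markers of 6 other cell types, of a like level. Their slopes on the granulocyte level were −0.0229 to 0.283, at most 0.490 with 2 SE added, where an equal rise needs 1. A part from such a share stays open, because the erythroid marker correlation was −0.0514 with a jackknife SE of 0.234, a spread that was allowed for only after the first output was seen. With the marker level as a covariate Saa3 stayed at 4.04 (SE 0.35, adjusted p = 7.41e-06) and Socs3 at 2.20 (SE 0.43, adjusted p = 0.00554). Lcn2 was at 1.40 (SE 0.37, adjusted p = 0.0272) and Lrg1 at 0.93 (SE 0.28, adjusted p = 0.0438), against 1.76 and 0.98 without it. For Lcn2 and Lrg1 the change less 2 SE was at least 0.25 in this fit and the 18 without 1 array. The changes in those 18 were 1.17 to 1.72 and 0.72 to 1.07, and the calls were lost in 3 and 12 (adjusted p up to 0.0881 and 0.114). This argues against the amount of granulocyte-lineage cells, as far as the marker level follows it, as the whole cause of these rises with LPS. The level averages markers as unlike as S100a9 and Mpo, with 1 slope for all groups. Saa3 followed this level on LPS arrays, at 7.85 to 8.45 on replicates 1 to 3 and 9.98 to 11.12 on replicates 4 to 6. With PBS, where the level ranged from 6.10 to 8.83, Saa3 was at 4.61 to 5.42. A slope shared by all groups may therefore take out too little of the rise of Saa3 with LPS. The covariate also cannot take out a response to LPS inside such cells, which stays open. A part of the rise of Lcn2 and Lrg1 from such cells stays open, because Lrg1 was under the bound of log2 1 set for this without the covariate too, as do, untested, a sorting session shared by some numbers and a response of the stem cells themselves.

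IFNa replicates 1 and 4 and LPS replicates 1 and 2 stood apart from their groups, with array weights of 0.664, 0.584, 0.572 and 0.574. A batch or handling that moves the same genes on all 4 is argued against, since the deviations of the IFNa pair correlated with those of the LPS pair at a mean of 0.0105 (−0.0600 to 0.0724). Shared handling that only adds noise would not show in these correlations and stays open. Higher background may account for the LPS pair, where 2 of 2 arrays (222 and 197) lay above the other 4 LPS arrays, and is argued against for the IFNa pair, where 0 of 2 did. No biological explanation was tested, because the labels divide the arrays of a group only by number.

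Chrnb1, Chst2, Itga9, Rprm and Matn4 were among the 10 largest falls with both treatments, although the other probe of Itga9 gave −0.94 with IFNa and 0.22 with LPS, and the IFNa call of Chrnb1 was lost without PBS replicate 3 or 6 or IFNa replicate 1, 2, 5 or 6 (adjusted p up to 0.0590). The medians of these genes (−3.40 with IFNa and −3.27 with LPS) lay below those of the stem cell genes (−0.35 and −0.52) by 3.04 and 2.75. A gap is in part given, since the 5 genes were chosen by their fall. The stem cell genes were not, and their lowest changes were −1.66 and −2.12. This argues against fewer stem cells in the treated samples as the whole cause, if the cells in their place lack the transcripts of the stem cell list, which was not tested. High values on a few PBS arrays are argued against too, since 4 of the 5 genes had all 6 PBS arrays above all 12 treated arrays, which chance gives in 0.00539% of genes not chosen by their fall, a share that does not hold for these, chosen by it. A treatment response shared by IFNa and LPS may account for them, as a hypothesis found and tested on the same data, and other technical causes were not tested.

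Of 405 groups of 6 values looked at, 36 held an array far from the other 5, where chance flags about 1 in 20 groups, or 20.2. LPS replicate 2 had 6 of these, IFNa replicates 3, 4 and 6 and LPS replicates 1 and 5 had 4 each, and 6 arrays had 0. The values are log2 levels. On PBS replicate 2 this held for Tmem53 at 4.84 (nearest other 7.47). PBS replicate 3 had Angpt1 at 11.12 (nearest other 10.73) and Phlda3 at 5.46 (nearest other 4.62). For PBS replicate 5 it was Nfkbiz at 9.17 (nearest other 8.45). On IFNa replicate 1 this held for Dnajb1 at 13.28 (nearest other 12.91) and Ier3 at 9.87 (nearest other 10.74). IFNa replicate 3 had H4c17 at 9.80 (nearest other 10.29), Lrp5 at 6.60 (nearest other 4.98), Prex2 at 6.58 (nearest other 4.32) and Vwf at 8.95 (nearest other 9.60). For IFNa replicate 4 it was Blvrb at 9.57 (nearest other 11.02), Ndn at 8.25 (nearest other 7.06), Rrp9 at 11.19 (nearest other 11.61) and Tap1 at 9.52 (nearest other 8.87). On IFNa replicate 6 this held for Egr1 at 11.42 (nearest other 11.08), Ngp at 10.00 (nearest other 5.59), Procr at 4.48 (nearest other 6.38) and S100a8 at 8.94 (nearest other 4.78). LPS replicate 1 had Angpt1 at 7.47 (nearest other 8.99), H2-T22 at 10.07 (nearest other 9.53), Ifi27 at 11.61 and Ifi27l2a at 6.73 (nearest other 7.86). For LPS replicate 2 it was Cfb at 6.61 (nearest other 7.84), Cxcl10 at 4.51 (nearest other 8.26), Gbp10 at 7.74 (nearest other 8.81), Lepr at 6.72 (nearest other 5.86), Mecom at 5.87 (nearest other 8.15) and Pcna at 5.52 (nearest other 6.75). On LPS replicate 3 this held for Cdca8 at 12.03 (nearest other 12.23) and Lrig1 at 5.58 (nearest other 7.79). LPS replicate 5 had Ier3 at 12.27 (nearest other 11.59), Lrg1 at 8.60 (nearest other 7.31), Nlrc5 at 11.36 (nearest other 11.06) and Rprm at 5.44 (nearest other 4.48). For LPS replicate 6 it was Cd40 at 5.06 (nearest other 5.76) and Traf1 at 8.21 (nearest other 5.71).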

How the results depend on the processing

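The tests without the 4 arrays of lowest weight, with the granulocyte marker score and with the numbers 1 to 3 against 4 to 6 as covariates were chosen only after the result was seen. The causes of the changes given here were not tested, except that a stricter threshold lowers counts by construction. The count for IFNa against PBS was 948 with array weights and 316 with a 2-fold minimum, and for LPS against PBS 609 with a 2-fold minimum and 920 without the 4 arrays. The count for LPS against IFNa was 587 with median scaling, 134 with detection on all 18 arrays, 87 with only the compared groups, 115 with array weights, 116 with a 2-fold minimum, 64 without the 4 arrays and 119 with the granulocyte marker score. The correlation was 0.694 with detection on all 18 arrays. Overlap up was 105 with a 2-fold minimum, and overlap down 260 with no background correction, 97 with median scaling, 286 with the authors' table, 246 with array weights and 70 with a 2-fold minimum. List tests past the threshold were 6 with an estimated correlation and 30 by fry, which kept 23 of the 26. With the mean of probes Ndufb8 (−0.14, adjusted p = 0.707) and Sdha (0.15, adjusted p = 0.797) reversed. Leaving out 1 array gave 399 to 637 genes for IFNa against PBS, 896 to 1526 for LPS against PBS (896 without PBS replicate 2 and 922 without PBS replicate 3) and 99 to 215 for LPS against IFNa (99 without LPS replicate 3, 105 without IFNa replicate 1, 118 without IFNa replicate 2, 120 without IFNa replicate 5 and 141 without LPS replicate 6). The same fits gave a correlation of 0.590 to 0.650, overlap up of 149 to 196, 23 to 30 list tests and overlap down of 85 to 170 (85 without PBS replicate 3, 86 without PBS replicate 2, 94 without PBS replicate 6 and 104 without IFNa replicate 6).

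Of 160 calls of named genes, Ifi27 included, 155 were kept with an offset of 50, 149 with no background correction, 151 with loess, 144 with median scaling, 147 with the authors' table, 139 with the mean of probes, 119 with only the compared groups, 104 without the 4 arrays and 125 to 144 without 1 array. With the granulocyte marker score 138 were kept, and 22 of the 26 list tests, with 1 gained. With the numbers as a covariate 155 were kept, and the counts were 590, 1416 and 207. The replicate number as a block gave 432, 1115 and 122 genes, overlap down of 104, and kept 130 of the 160 gene calls. The numbers were not taken to pair the samples, since 0 of 18 same-number pairs correlated over 0.1 (−0.0262 to 0.0876) and 5 of 18 matched their own number best, although the 6 pairs of IFNa with LPS arrays were all above 0 (0.0154 to 0.0876) and 4 of these 6 matched best. A chip block was not run, because the chip of each array is not given in the sources used here. Signal over background limits the falls, since a gene that drops to the background of 172 to 222 gives only a bound.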

Other observations

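Among the tests in this part, those of the complement, apolipoprotein L and chemokine families were chosen only after the result was seen, and permutation within groups was chosen after a first output with free permutation.

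Other families near the interferon response moved as well. Complement genes, which tag microbes for destruction, had 3 of 14 members up with each treatment, C4a, C4b and Cfb, the first pair being near-identical copies. C4b rose by 3.06 with IFNa and 3.22 with LPS, and the family passed camera in both (larger adjusted p = 0.0193, and adjusted p = 0.164 with an estimated correlation), although its IFNa median was −0.04. Its IFNa call was lost with median scaling (0.0584), no background correction (0.0784) and the authors' table (0.0971), and its LPS call with the last of these (0.0564) and no background correction (0.054). Apolipoprotein L genes had medians of 1.77 with IFNa and 0.94 with LPS (larger adjusted p = 0.00956, and adjusted p = 0.107 with an estimated correlation), led by Apol9b at 4.95 and 3.11. Of the 4 members 2 rose with IFNa and only 1, Apol9b, with LPS. Schlafen genes rose with IFNa, with 2 of 6 up (adjusted p = 0.000428), and were at an adjusted p of 0.385 with LPS. Chemokine genes had the same 3 of 11 up with each treatment, Ccl5, Cxcl9 and Cxcl10, and passed with LPS (adjusted p = 0.0180, adjusted p = 0.124 with an estimated correlation, and lost with the authors' table at 0.0607) and not with IFNa (adjusted p = 0.105). PARP genes (larger adjusted p = 0.945) and TRIM genes (0.667) passed with neither.

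The 53 histone genes had a median of 0.11 with IFNa, where 1 rose (adjusted p = 0.0152, and adjusted p = 0.593 with an estimated correlation), and of −0.19 with LPS, where 2 rose and 6 fell (adjusted p = 0.00259, and adjusted p = 0.540 with an estimated correlation). Between LPS and IFNa their median was −0.29 (adjusted p = 4.00e-11, and adjusted p = 0.177 with an estimated correlation).

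The antiviral response to LPS may be a scaled form of that to IFNa. Over the 36 antiviral genes, which are not independent, the fold changes against separate PBS arrays correlated at 0.823 (0.677 to 0.903 over 20 assignments), with a slope of 0.636. The median ratio of LPS to IFNa changes was 0.624.

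Across the 18 arrays, with group means removed, the granulocyte marker level was set against 6 other marker lists by permutation within groups. It correlated with the monocyte list at r = 0.665 (permutation p = 0.0120, adjusted p = 0.0544) and rho = 0.703 (permutation p = 0.00553, adjusted p = 0.0332), and at r = 0.545 without the 2 arrays farthest from the median. The endothelial list gave r = 0.477 (permutation p = 0.0181, adjusted p = 0.0544) and rho = 0.463 (permutation p = 0.0443, adjusted p = 0.133). The other 4 lists had r of −0.0514 to 0.341.

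The counts of changed genes, the list tests, the correlation and the overlaps of the treatments were recomputed in 100 splits of the arrays, the real one included, with no correction for the 84 list tests. With 100 splits the smallest share a result can reach is 1 in 100, which is too coarse for such a correction. Chance can be excluded for the counts of changed genes, 574, 1440 and 212, where 1 split in each case was as large and the highest other count was 4. For the overlaps of 199 up and 157 down the highest other was 1, but splits that call hardly any genes can hardly overlap, so nothing is drawn from these on the sharing of calls. Chance cannot be excluded for the correlation of 0.626, where 7 splits were as large and the highest other was 0.729.

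With IFNa, no permutation split but the real one was as extreme for antiviral genes (unadjusted camera p = 6.18e-65, lowest other 1.91e-33). The same held for GTPases (2.75e-23, 6.04e-17), MHC class I (1.49e-16, 1.20e-12) and HSC genes (8.52e-05, 0.000181). Another permutation split gave a lower p for MHC class II (2.75e-06, 1.40e-07) and ribosomal protein genes (0.0146, 0.0128), with 2 splits each. All of these list calls lay under the bound of 5 splits but were not corrected for the 84 list tests. Of these calls, 3 were lost with an estimated correlation: MHC class II (adjusted p = 0.0866), HSC (adjusted p = 0.204) and ribosomal protein genes (adjusted p = 0.292), the last also with median scaling and in 9 of the fits without 1 array. Chance cannot be excluded for MYC (0.000645, 0.000101), quiescence (0.00234, 0.000329) and p53 genes (0.0111, 0.00118), with 5, 6 and 7 splits.

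With LPS, no split but the real one was as extreme for antiviral (3.16e-29, 1.43e-22) and MHC class I genes (5.15e-09, 4.38e-08). Another split gave a lower p for GTPases (2.09e-13, 1.24e-16), quiescence (3.38e-05, 1.92e-05) and megakaryocyte genes (0.000254, 0.000132), with 2 splits each, under the bound of 5 but not corrected. The calls of the last 3 lists were lost with an estimated correlation (adjusted p = 0.08, adjusted p = 0.08 and adjusted p = 0.19). Chance cannot be excluded for HSC genes (1.80e-06, 3.71e-08) and erythroid markers (0.00167, 0.000530), with 5 each, MHC class II (0.000785, 3.74e-06) with 8, mitotic (0.000520, 7.78e-07) with 12 and STAT3 genes (0.00960, 0.000274) with 13.

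Between LPS and IFNa, no split but the real one was as extreme for antiviral genes (9.51e-24, 3.50e-16). Other splits gave a lower p for mitotic genes (1.15e-06, 1.37e-09), with 3 splits, and megakaryocyte genes (2.36e-05, 8.50e-06), with 4, under the bound of 5 but not corrected. The mitotic and megakaryocyte calls were lost with an estimated correlation (adjusted p = 0.112 for each). Chance cannot be excluded for MHC class I genes (0.00642, 0.00123) with 5, GTPases (0.000560, 1.11e-09) with 17, granulocyte markers (0.000795, 8.45e-09) with 20 and erythroid markers (0.00518, 6.16e-07) with 32.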
